A study of Mus musculus with 2 samples.

How the data were processed

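Poly-A RNA-seq of adult mouse liver was analysed from processed files of 2 libraries, biological replicates 1 and 2 of 1 group. Per the labels, the libraries are strand-specific, read in pairs of 76 nucleotides, and were made from poly-A RNA longer than 200 nucleotides after depletion of ribosomal RNA, with external spike-in RNAs added. The labels also name the molecule as total RNA. Groups and replicate numbers were taken from the labels.

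Each library has a deposited gene table and transcript table. Per the file headers and the accompanying notes, the authors quantified reads on mm10 with GENCODE annotation M4. The columns carry the names that RSEM writes, but the quantification tool, its version and the aligner are not given in the sources used here. The deposited estimated counts are read pairs per gene that need not be whole, because reads that match several genes are shared among them. The deposited TPM values are estimates divided by effective length and scaled to 1 fixed sum per library over all entries, spike-ins included. The deposited FPKM values were not used here. The deposited percent per transcript is its share of its gene's TPM. The posterior standard deviation of the estimated count, a score per gene given by the authors, was used to find genes whose reads are shared with copies. The intervals of TPM, also deposited, were not used because their level is not stated.

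The deposited splice junction counts and contig signal levels are in files of the whole series on mm9, per the file headers. The junction file gives reads of libraries called R1 and R2, which are not matched here to the labelled replicates, and flags that it does not explain. The reproducibility score of both files was deposited by the authors, and its calculation is not given in the sources used here. No coordinate was moved between builds.

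Symbols, coordinates and gene types came from GENCODE M21 on GRCm38, the same assembly as mm10, matched by stable identifier. Of 43346 genes listed 42462 matched. The 884 others held 0.0691% and 0.0766% of TPM in replicates 1 and 2 and were kept without a name. The tables also list 26248 entries with numeric identifiers and 1 phage control, all at 0 reads, and 96 spike-ins with 1094063 and 1088802 reads. These entries stayed out of gene counts and scaling. Library totals were 60770411 and 61688916 estimated reads. Spike-ins held 2.56% and 2.52% of TPM. The median difference between length and effective length was 188 and 178 bases in replicates 1 and 2 over genes with an effective length above 1000 bases. Effective length sets TPM, most of all for short genes. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

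A gene was called detected at TPM 1 or more, and absent below 0.1 TPM. For a count of 0, the upper limit is 3 reads. Shares of TPM are given as mean and SD of the libraries. Estimated counts were rounded and scaled by TMM in edgeR 4.0.16 (R 4.3.3). Each gene with at least 20 reads in both libraries together was compared by a two-sided exact conditional binomial test with Benjamini-Hochberg adjustment at 0.05. That test asks whether the libraries differ by more than counting error. It says nothing of conditions, of which there is 1. Log2 ratios used a prior count of 0.5 reads. They come from reads, so they can differ from the ratio of TPM where the effective length of a gene differed between libraries. The biological coefficient of variation came from edgeR's common dispersion. For each gene list the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the 200 genes nearest in abundance to each member.

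The comparisons, the 47 gene lists, the alternatives and the rule for named genes were set before the data were examined. The text names the 15 nuclear and 5 mitochondrially encoded genes with the highest mean TPM, the 2 most abundant members of each list with up to 2 more where a list is discussed, and the 10 genes with the largest ratio in each direction that passed the exact test at mean TPM 10 or more outside the mitochondrial genome. Some genes that this rule selects are not reported here. The text also names all Y-linked and X inactivation genes, 12 genes for isoforms, and the 5 leading junctions and contigs. Ddx3x, Eif2s3x, Kdm5c and Kdm6a were chosen after the values were seen, as homologues of the Y-linked genes.

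The steps were tested on simulated data. With counts drawn at the means and depths of the libraries and 200 genes changed, the exact test over 14535, 14532 and 14509 genes recovered 72.9%, 87.0% and 100.0% of changes of 1.5, 2 and 4-fold, with 3.97%, 3.87% and 2.44% false among the calls. These draws held counting error alone, without spread between replicates. The false shares therefore do not describe the calls made on the real libraries. Simulated coefficients of variation of 10, 20 and 40% were returned as 10.0%, 20.0% and 39.4%. Of 200 unshifted random lists of 12 genes 3.50% fell outside the middle 95%, and 95.0% did after a shift of 0.5 on the log2 scale. The ratios were permuted for this, which removes any joint movement of genes. Trends in GC content and transcript length were removed by lowess curves over 14448 genes, which in simulation brought the correlation with an added trend from 0.324 to 0.0031. The form of this correction was settled after a first run on the data, in which a simpler form had left part of the simulated trend.

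Alternatives included other detection limits, TPM rescaled without mitochondrial genes and spike-ins, shares of reads, posterior mean TPM, each library alone, other pseudocounts and filters, DESeq2 1.42.0 size factors, total reads and spike-in totals, TPM ratios, lists without their most abundant member, and a stricter reproducibility score of 0.1. The score of 0.1, list medians with total reads, the count of lists at 1% or more of TPM, and the counts of list members under all scalings were chosen after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.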

Results

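Polyadenylated RNA of adult mouse liver was sequenced in 2 libraries, labelled biological replicates 1 and 2 of 1 group. The tissue is labelled as 8-week-old C57BL/6J liver, a common inbred laboratory strain, pooled from male and female littermates. Both libraries carry 1 donor identifier, and whether the replicates came from separate animals is not given in the sources used here. Differences between them therefore measure only the spread between these 2 samples, which may be technical. The libraries held 60770411 and 61688916 estimated reads in replicates 1 and 2, spike-ins included. At this depth 1 read on a gene of 1000 bases corresponded to 0.0205 and 0.0204 TPM, the length-scaled transcript abundance, and the limit set by 3 reads to 0.0615 and 0.0611 TPM. The design holds no contrast between conditions, so the text describes the composition of the liver transcriptome and how far the replicates differed.

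Transcripts of secreted plasma proteins and of mitochondrial respiratory chain subunits dominated both libraries. Apolipoprotein E (Apoe, ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand, GRCm38) was the most abundant transcript on average at 35066 ± 1736 TPM (SD, n = 2), followed by albumin (Alb, ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand) at 33438 ± 1873 TPM. Transferrin (Trf), the iron carrier of plasma, followed at 25800 ± 4365 TPM, the mitochondrially encoded cytochrome c oxidase subunit mt-Co1 at 25401 ± 210 TPM, and apolipoprotein A-II (Apoa2) at 24324 ± 1007 TPM. Fetuin-A (Ahsg) had 14721 ± 65.5 TPM, the ferritin light chain Ftl1 11285 ± 612 TPM, transthyretin (Ttr) 8484 ± 1150 TPM, Apoc3 7702 ± 495 TPM, the glutathione peroxidase Gpx1 7515 ± 520 TPM and the antitrypsin gene Serpina1b 7305 ± 98.8 TPM. After mt-Co1, the most abundant mitochondrially encoded mRNAs were mt-Co3 (10467 ± 1486 TPM), mt-Atp6 (5433 ± 880 TPM), mt-Cytb (5049 ± 1402 TPM) and mt-Co2 (3266 ± 895 TPM).

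Several of the 15 most abundant nuclear entries were not liver mRNAs. The lincRNA Gm42418 (chromosome 17, 39846958 to 39848788), known to overlap ribosomal RNA sequence, had 25755 TPM in replicate 1 and 10499 TPM in replicate 2. The signal recognition particle RNA genes Rn7s1 and Rn7s2, near-identical copies on chromosome 12, were each listed at 5411 and 13467 TPM in replicates 1 and 2. Gm29216 and Gm10222, unprocessed pseudogenes next to each other on chromosome 1, had 18052 ± 2071 and 9050 ± 178 TPM. Such pseudogenes share sequence with the mitochondrial genome, so the origin of the reads listed on Gm29216 and Gm10222 is uncertain. The split of reads is also uncertain for mt-Co2, mt-Co3 and mt-Atp6, as it is between Rn7s1 and Rn7s2.

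The 10 most abundant genes held 21.7% ± 1.72 of TPM (SD, n = 2), the 100 most abundant 50.5% and 49.5% in replicates 1 and 2, and the 1000 most abundant 79.8% ± 0.792. At TPM 1 or more, 10701 of the 43346 genes listed were detected in both libraries, among them 10176 protein-coding genes, 74 lincRNAs, 74 antisense genes and 228 pseudogenes. Of the 10701 genes, 1033 reached 100 TPM in both libraries and 121 reached 1000 TPM. Nuclear protein-coding genes held 82.7% ± 0.897 of TPM and mitochondrially encoded genes 6.05% ± 0.736. Unprocessed pseudogenes, Gm29216 and Gm10222 among them, held 3.28% ± 0.185. Shares of mitochondrially encoded genes given here may be understated where reads of shared sequence went to such pseudogenes.

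Fixed gene lists give the composition by function. The 26 plasma protein genes, all at TPM 1 or more in both libraries, held 21.1% ± 0.476 of TPM. Coagulation genes (15 found) held 1.32% ± 0.132, led by antithrombin (Serpinc1, 4474 ± 752 TPM) and fibrinogen gamma (Fgg, 2287 ± 194 TPM). Complement genes held 0.694% ± 0.0342, with C3 at 3232 ± 94.8 and C8g at 774 ± 49.1 TPM. The acute phase list held 0.458% ± 0.0206, most of it haptoglobin (Hp, 2134 ± 149 TPM) and Itih4 (939 ± 21.8 TPM). The 12 iron and heme genes held 2.83% ± 0.349, with the hepcidin genes Hamp2 and Hamp, the latter a regulator of iron export, at 6444 ± 1585 and 5641 ± 1620 TPM beside Ftl1. The major urinary protein family, pheromone carriers with closely related copies whose reads can be split wrongly, held 0.279% ± 0.0386, led by Mup14 (1284 ± 97.53 TPM) and Mup3 (914 ± 349 TPM), and 2 of its 21 genes were below 0.1 TPM in both libraries.

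Among metabolic lists, amino acid catabolism held the largest share, 1.98% ± 0.294 of TPM, led by the methyl-group regulator Gnmt (4210 ± 3.27 TPM) and the tyrosine-degrading dioxygenase Hpd (3772 ± 853 TPM). Xenobiotic cytochromes P450 held 1.09% ± 0.0886, led by Cyp2e1 (2125 ± 69.7 TPM) and Cyp2f2 (1851 ± 331 TPM), and conjugating enzymes 0.733% ± 0.0995, led by Gstm1 (2907 ± 503 TPM). Bile acid synthesis and transport held 0.568% ± 0.0554, with the ligase Slc27a5 at 1822 ± 230 and the bile acid uptake transporter Slc10a1 at 993 ± 116 TPM. The urea cycle held 0.510% ± 0.0410, with Ass1 at 3164 ± 254 and Cps1, its first enzyme, at 641 ± 0.403 TPM. Lipogenesis and glucose use held 0.402% ± 0.102 (Scd1, 1526 ± 537 TPM, and Fasn, 638 ± 176 TPM), fatty acid oxidation and ketogenesis 0.392% ± 0.0262, cholesterol synthesis and uptake 0.309% ± 0.00041 (Sc5d, 720 ± 62.7 TPM) and gluconeogenesis 0.222% ± 0.0341 (Fbp1, 1423 ± 126 TPM, and Pck1, 349 ± 201 TPM). The endocrine and growth axis held 0.642% ± 0.0238, led by Igfbp4 (1888 ± 442 TPM) and angiotensinogen (Agt, 1325 ± 149 TPM), with insulin-like growth factor 1 (Igf1) at 1148 ± 134 TPM. Liver transcription factors held 0.225% ± 0.00443, led by Cebpa (312 ± 18.7 TPM) and Rxra (262 ± 10.9 TPM), and the nuclear receptor Hnf4a had 243 ± 27.3 TPM. Pericentral genes held 0.541% ± 0.0503, periportal genes 1.01% ± 0.0887, interferon response genes 0.0890% ± 0.0132, replication-dependent histones 0.152% ± 0.0365, small structural RNAs 2.25% ± 1.23, the mitochondrially encoded mRNAs 5.99% ± 0.734 and the mitochondrially encoded rRNAs 0.0551% ± 0.0012. Clock genes that peak with Bmal1 held 0.0034% ± 0.00082, those that peak with Dbp and Per 0.0155% ± 0.00206 and immediate early genes 0.0131% ± 0.00217. Cytosolic ribosomal proteins held 2.72% ± 0.156, led by Rplp1 (4851 ± 608 TPM) and Rps2 (1954 ± 94.4 TPM), and heat shock genes 0.344% ± 0.00148, led by Hspa8 (2094 ± 60.6 TPM) and Hspa5 (1197 ± 56.5 TPM).

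**Figure D1:**
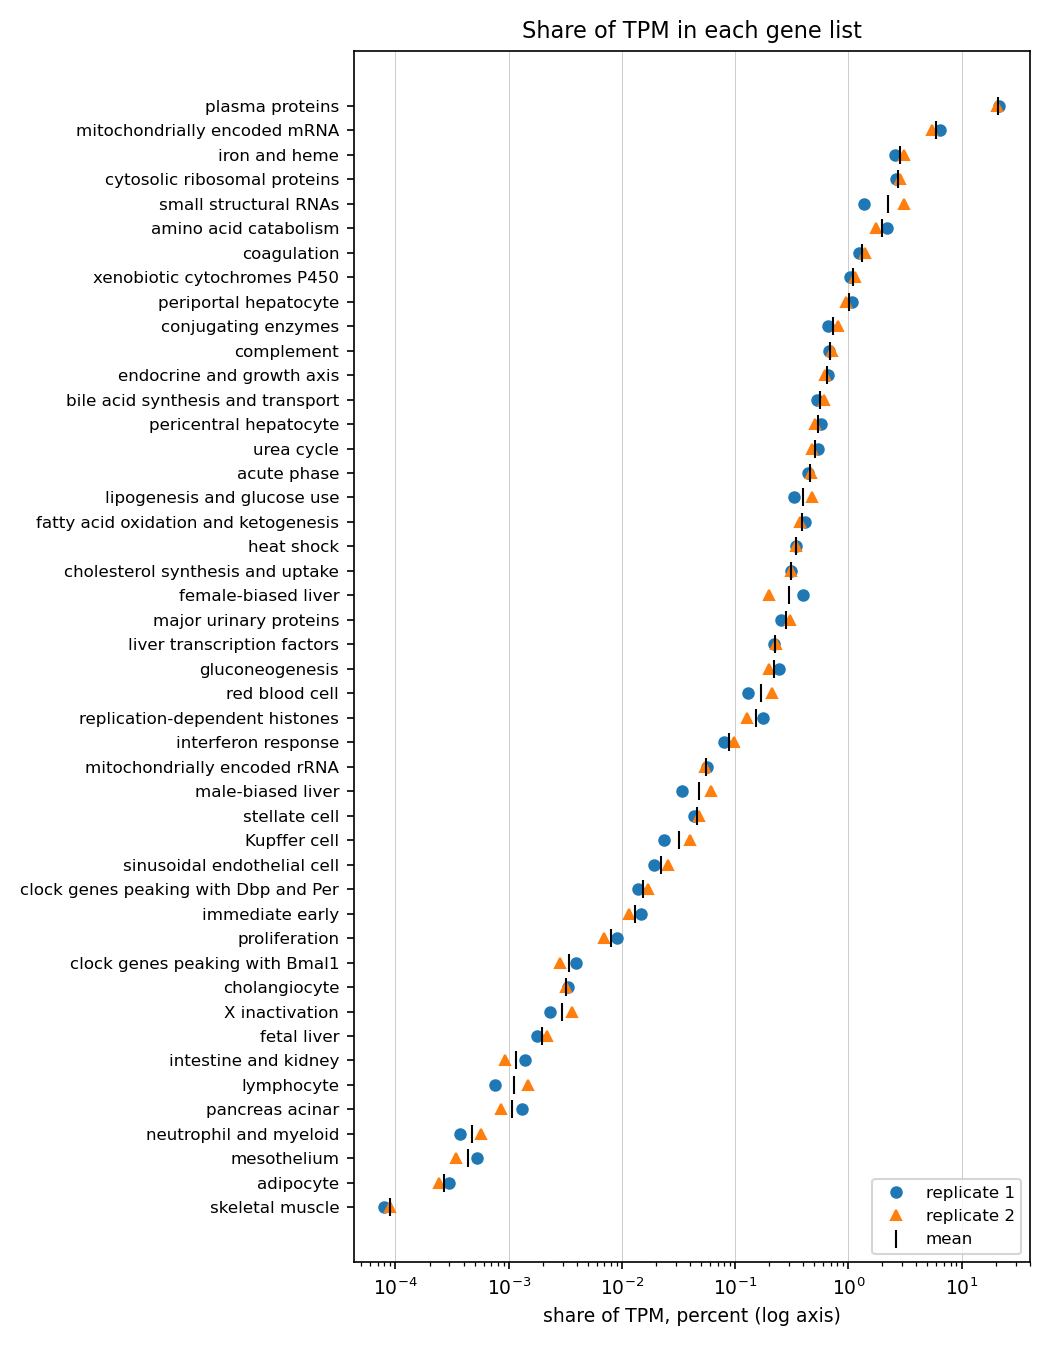
Share of TPM in each gene list, in percent on a log axis, for replicate 1 (circles), replicate 2 (triangles) and their mean (bars), with the Y-linked list left out because it stood at 0. Plasma protein genes held 21.1% of TPM on average, and lists of non-hepatocyte markers lay below 0.2% on average.

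Markers of cells other than hepatocytes were present at low levels. Kupffer cell genes, markers of the resident macrophages of liver, held 0.0319% ± 0.0117 of TPM, led by the complement genes C1qc (72.7 ± 24.2 TPM) and C1qb (62.0 ± 20.4 TPM). Sinusoidal endothelial genes held 0.0223% ± 0.00459 (Clec4g, 45.3 ± 6.13 TPM, and Stab1, 36.0 ± 12.4 TPM) and stellate cell genes 0.0459% ± 0.00308 (Ecm1, 310 ± 17.6 TPM, and Dcn, 70.1 ± 8.80 TPM). Most of the stellate share was Ecm1, while the median member had 5.365 TPM, so these shares do not rank the cell types. Cholangiocyte genes, markers of bile duct cells, held 0.00324% ± 0.00009 (Spp1, 15.3 ± 1.26 TPM), with 2 of 9 below 0.1 TPM in both libraries, and mesothelial genes 0.00044% ± 0.00013 (Upk3b, 2.17 ± 0.721 TPM, and Msln, 0.995 ± 0.474 TPM). Red blood cell genes held 0.170% ± 0.0580, nearly all of it globin mRNA (Hba-a2, 626 ± 171 TPM, and Hbb-bs, 525 ± 184 TPM). Lymphocyte genes held 0.00111% ± 0.00050 (Cd79a, 3.28 ± 2.33 TPM, and Cd79b, 2.25 ± 1.48 TPM) and neutrophil and myeloid genes 0.00047% ± 0.00014 (Csf3r, 1.80 ± 0.941 TPM, and S100a8, 0.840 ± 0.240 TPM).

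Genes of neighbouring tissues were at low levels. Pancreas acinar genes held 0.00108% ± 0.00033 of TPM (Cela2a, 3.58 ± 0.799 TPM, and Ctrb1, 4.40 and 1.61 TPM in replicates 1 and 2), intestine and kidney genes 0.00116% ± 0.00032 (Fabp2, 8.59 ± 3.92 TPM, and Muc2, 2.56 ± 0.841 TPM, with 5 of 9 below 0.1 TPM in both libraries), adipocyte genes 0.00027% ± 0.00004 (Fabp4, 2.13 ± 0.0990 TPM, and Cfd, 0.530 ± 0.438 TPM, with 5 of 7 below 0.1 TPM) and skeletal muscle genes 0.00009% ± 0.00001 (Mylpf, 0.270 ± 0.283 TPM, and Ckm, 0.165 ± 0.0919 TPM, with 5 of 9 below 0.1 TPM). The fetal liver list held 0.00198% ± 0.00030, led by Meg3 (14.7 ± 4.23 TPM) and Cdkn1c (2.27 ± 1.03 TPM). Proliferation genes held 0.00800% ± 0.00156, led by Tk1 (48.8 ± 13.7 TPM) and Pcna (18.3 ± 0.771 TPM).

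No read was assigned to any of the 4 Y-linked genes in either library, although the tissue is labelled as pooled from both sexes. Ddx3y, Eif2s3y, Kdm5d and Uty, which are broadly expressed in male tissues, were at 0 reads, and a count of 0 allows at most 0.0232, 0.0568, 0.0174 and 0.0221 TPM in replicate 1 and 0.0229, 0.0558, 0.0173 and 0.0219 TPM in replicate 2. Their X-linked homologues had many reads, with 3223 and 3135 for Ddx3x, 6177 and 6263 for Eif2s3x, 5991 and 7190 for Kdm5c and 643 and 666 for Kdm6a in replicates 1 and 2. Over all 1569 genes listed on chromosome Y, replicate 1 had 0 reads and replicate 2 had 1 read. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, minus strand), the RNA that silences 1 X chromosome in female cells, had 23.4 TPM (18451 reads) in replicate 1 and 35.9 TPM (26061 reads) in replicate 2. Genes known to be expressed more in female than in male liver held 0.298% ± 0.140 of TPM, led by A1bg (1879 TPM in replicate 1 and 355 TPM in replicate 2) and Cyp2c69 (482 and 369 TPM). Genes known to be expressed more in male liver held 0.0476% ± 0.0193, led by Nudt7 (196 and 252 TPM) and Cyp2d9 (85.6 and 135 TPM).

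**Figure D2:**
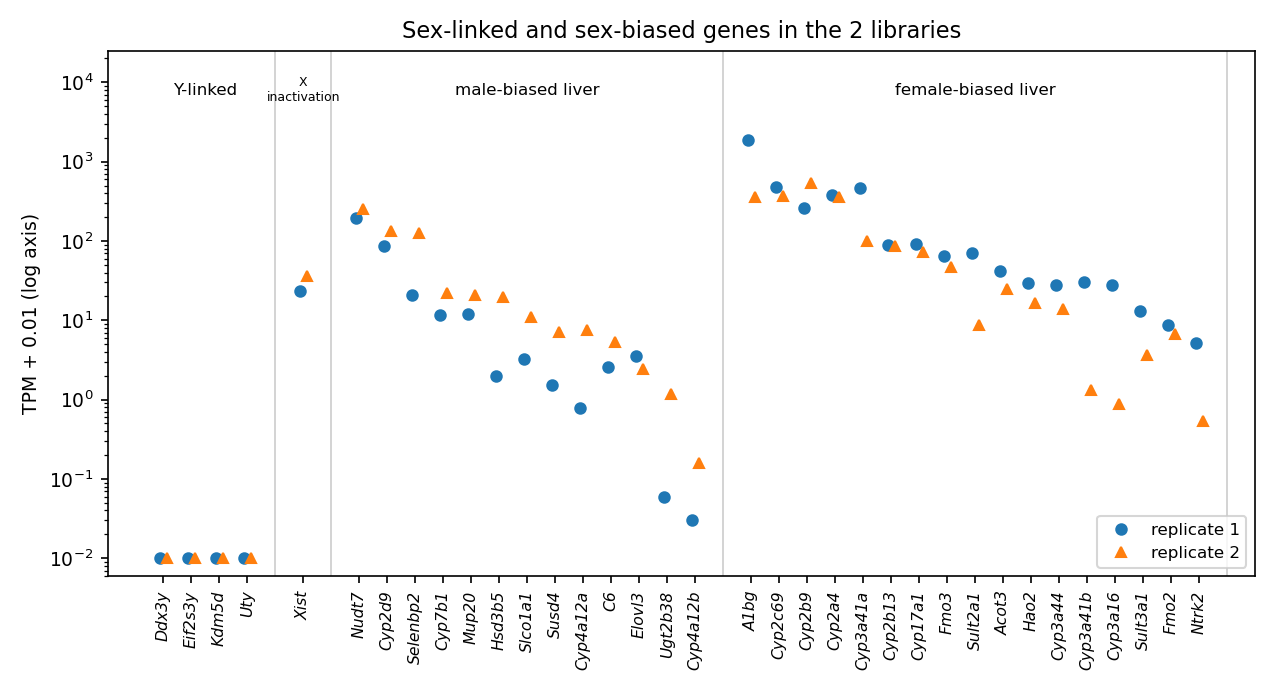
TPM + 0.01 on a log axis for the genes of the Y-linked, X inactivation, male-biased and female-biased lists, in replicate 1 (circles) and replicate 2 (triangles). All 4 Y-linked genes lie at 0 TPM, Xist lies at 23.4 and 35.9 TPM, and 16 of 17 female-biased genes were higher in replicate 1 by the exact test.

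At the isoform level, 90.7% of 4107 multi-isoform genes at mean TPM 10 or more (3726 genes) had the same most abundant isoform in both libraries. For 996 of these genes that isoform held at least 90% of the gene in both libraries, and the median share of the most abundant isoform was 71.5% and 70.4% in replicates 1 and 2. Hnf4a was split between Hnf4a-201 (58.1% ± 5.68 of the gene, n = 2) and Hnf4a-202 (40.7% ± 5.83). Fibrinogen gamma was mostly Fgg-202 (87.8% ± 1.05), Pkm mostly Pkm-201 (86.4% ± 4.55) and Ppara mostly Ppara-202 (66.4% ± 1.02). Fibronectin (Fn1), with 17 isoforms, had no isoform above 25.4% ± 2.68. Alb and Cps1 are annotated with 1 isoform each in the files. For some genes a short or partial model took a large share of TPM, and the cause was not tested. Apob-203, a 2174-base model of the 3′ part, took 69.9% ± 1.24 of Apob against 29.7% ± 1.28 for the 13934-base Apob-202. Igf1-208, of 510 bases, took 83.5% ± 1.49 of Igf1, Pklr-203, of 349 bases, took 54.6% ± 8.97 of liver pyruvate kinase, and the 1675-base retained-intron model Insr-202 took 47.0% ± 0.983 of the insulin receptor, beside 53.0% ± 0.983 for the full-length Insr-201.

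The libraries were next compared with each other, which asks how far these 2 libraries, labelled biological replicates, differ. Female-biased genes, amino acid catabolism and replication-dependent histones were lower in replicate 2, whereas male-biased, interferon, Kupffer cell and lipogenic genes were higher. Retinoic acid oxidase Cyp26a1 (chromosome 19, 37697798 to 37701536, plus strand) had 168 TPM in replicate 1 and 6.11 TPM in replicate 2, and the cytochrome P450 gene Cyp2c39 231 and 2.58 TPM. In the opposite direction Igfbp2, which binds insulin-like growth factors, had 187 and 868 TPM. Most genes differed far less. Across 11153 genes at mean TPM 1 or more, Pearson's r of log2(TPM + 1) was 0.979 and Spearman's rho 0.971, as correlations across genes, which are not independent replicates. Of 5481 genes at mean TPM 10 or more, 91.5% lay within 1.5-fold and 113 were at least 2-fold apart, with a median absolute log2 ratio of 0.19.

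By the two-sided exact conditional binomial test with Benjamini-Hochberg adjustment, 8301 of 14533 genes differed by more than counting error, 4124 higher in replicate 2 and 4177 higher in replicate 1. The test compares these 2 libraries, not conditions, and replicate spread alone can pass it at this depth. Of the genes that passed, 778 were at least 2-fold higher in replicate 2 and 340 at least 2-fold higher in replicate 1. The balance of directions depends on the scaling. With TMM scaling 49.7% of calls were higher in replicate 2, against 69.4% with total reads and 73.6% with spike-in totals, as the median log2 ratio of all genes was 0.13 and 0.15 with these against 0.00 with TMM. The ratios given here are relative to TMM scaling. The biological coefficient of variation, the spread between replicates beyond counting error, was 24.1% on 1 residual degree of freedom per gene.

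**Figure D3:**
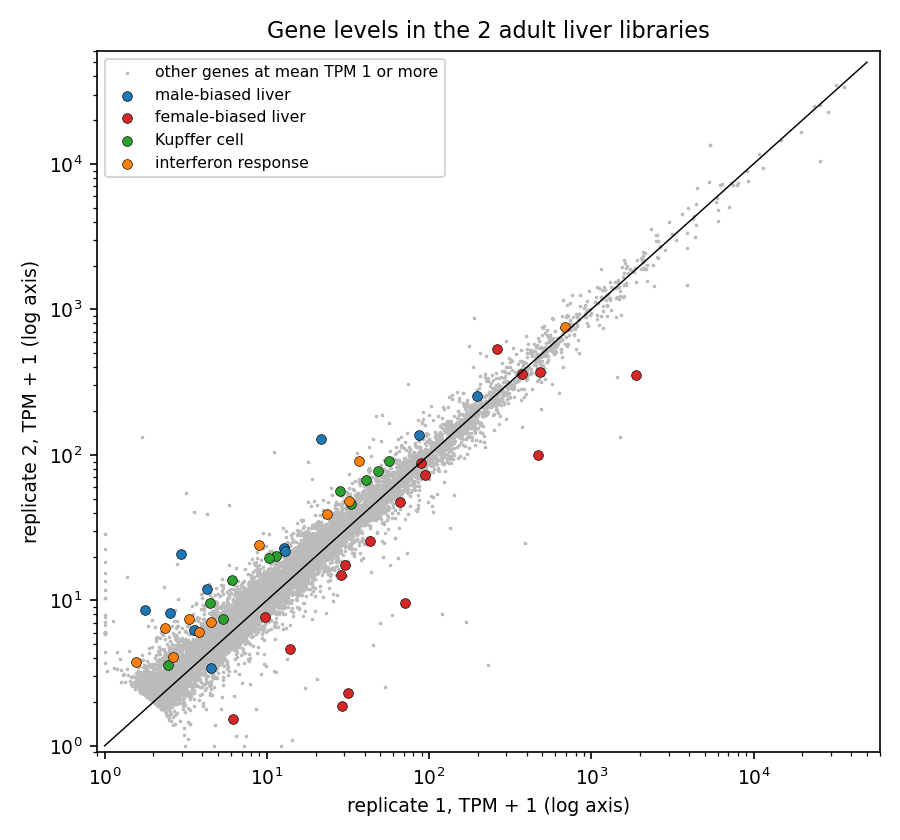
TPM + 1 of each gene at mean TPM 1 or more in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with 4 gene lists in colour and the line of equality. Pearson's r across genes was 0.979, and the coloured female-biased genes lie mostly below the line.

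Named next are the genes with the largest ratios, 10 in each direction, among those at mean TPM 10 or more that passed the exact test. Higher in replicate 2 were Eno1b (ENSMUSG00000059040, chromosome 18, 48045335 to 48048412, plus strand), a processed copy of the glycolytic enzyme gene Eno1, at 0.690 and 130.87 TPM (log2 ratio 7.42), the steroid dehydrogenase Hsd3b5 at 1.97 and 19.9 TPM (3.21), the selenium-binding Selenbp2 at 20.6 and 128 TPM (5.66-fold), Mup11 at 17.0 and 88.2 TPM (2.28) and Igfbp2 (2.09). The remainder were the pseudogenes Gm12191 (4.53), Serpina4-ps1 (3.80), Gm13456 (3.41), Gm10263 (3.37) and Gm26712 (3.37), the last on only 7 and 85 reads. Higher in replicate 1 were Cyp2c39 (log2 ratio -6.61) and its paralog Cyp2c38 (-3.20), Mup1 (-5.31) and Mup9 (-3.71), Cyp3a16 (-5.10) and Cyp3a41b (-4.66), Cyp26a1 (-4.90), the metallothionein Mt2 at 119 and 7.11 TPM (-4.16), the pseudogene Gm10221 (-3.45) and Abhd1 (-3.23). For the Mup genes, Cyp3a41b, Eno1b and the pseudogenes other than Serpina4-ps1, reads may be split between near-identical copies, so their ratios are uncertain.

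Of 41 lists with at least 4 members tested, 19 had a median ratio outside the middle 95% of 10000 random lists matched on mean expression. Lists of unrelated genes would give 2.05 by chance, but the genes of a list can move together. Some genes, such as Gls2, are in more than 1 list, so the 19 are not separate excesses over chance. The percentile describes these 2 libraries and is not a test across animals. Counts of members below are with TMM scaling, and where total reads or spike-in totals lose members the number that kept direction and call under all scalings follows. Male-biased genes had a median log2 ratio of 1.60, with 12 of 13 members higher in replicate 2 by the exact test and 13 passing when adjusted over the list alone. The median was 0.82 over the 10 members with a posterior SD of at most 1% of their reads. Selenbp2 (5.66-fold), Cyp7b1 (log2 ratio 0.77) and Cyp2d9 (0.54) were among them, and the exception was Elovl3 (-0.67), named after its value was seen. Female-biased genes had a median of -0.94, with 16 of 17 higher in replicate 1, 15 of them under all scalings, and 17 passing adjusted over the list alone. A1bg (-2.53) and Cyp2c69 (-0.51) were higher in replicate 1, and the exception was Cyp2b9, higher in replicate 2 (0.91).

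Kupffer cell, interferon response, sinusoidal endothelial and red blood cell genes were higher in replicate 2. All 12 Kupffer cell genes were higher (median 0.76, 12 adjusted over the list alone), with Cd5l at 0.89 and C1qc at 0.57. Of 12 interferon response genes 11 were higher (median 0.98, 12 adjusted over the list alone), Irf7 by 1.19 and Isg15 by 0.66 on the log2 scale, and Bst2, the most abundant, had a ratio of 0.03 (adjusted p = 0.065, exact test). Of 13 sinusoidal endothelial genes 9 were higher and 2 lower (median 0.35, 11 adjusted over the list alone), with Stab1 at 0.60 and Ehd3 at -0.33. Of 7 red blood cell genes 4 were higher and 1 lower (median 0.42, 5 adjusted over the list alone). The 4 higher were all globin genes (0.37 to 0.94). Alas2, named after its value was seen, had 40.3 TPM in replicate 1 and 35.1 TPM in replicate 2. Other cell types moved differently. Stellate cell genes had a median of 0.03, at percentile 71.8, with 6 of 13 higher and 3 lower, of which 1 under all scalings, and 9 adjusted over the list alone. Cholangiocyte genes had a median of -0.32 (1 of 7 higher, 2 lower, 3 adjusted over the list alone, percentile 10.5 once a trend with GC content and length was removed), mesothelial genes of -0.82 (3 of 5 lower, 2 under all scalings, 3 adjusted over the list alone) and pancreas acinar genes of -1.37 (5 of 7 lower, 5 adjusted over the list alone), all of low abundance, and mesothelial genes had percentile 2.695 with TPM ratios. Lymphocyte genes (median 0.55, percentile 90.8, 4 of 12 higher and 1 lower, 5 adjusted over the list alone) and neutrophil genes (median 0.68, percentile 79.5, 1 of 4 higher and 1 adjusted over the list alone) lay inside the random range.

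**Figure D4:**
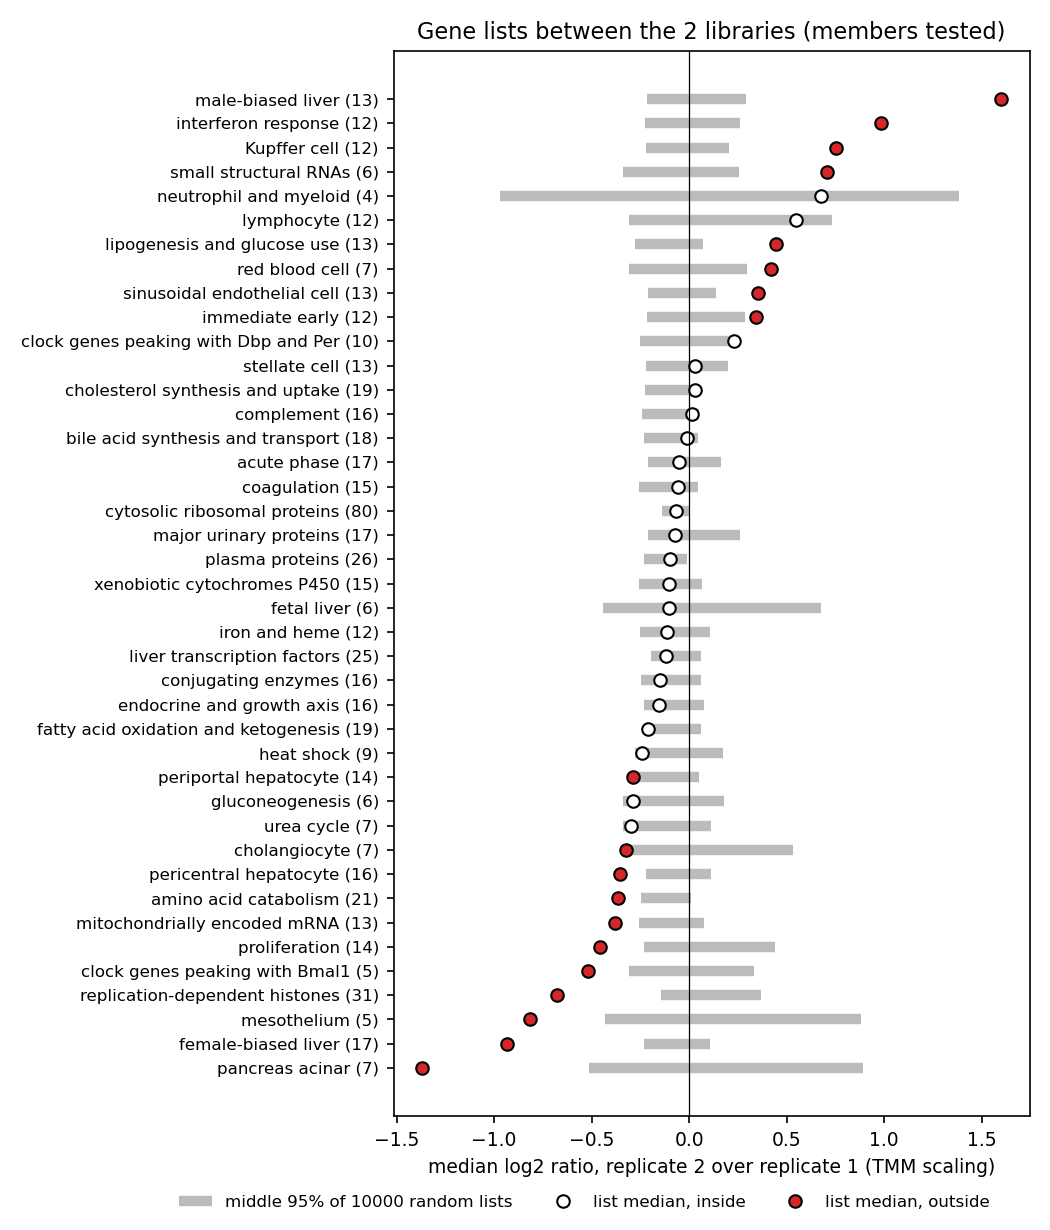
Median log2 ratio of replicate 2 over replicate 1 for each of 41 gene lists (points, number of members tested in brackets), with the middle 95% of 10000 random lists matched on expression (grey bars). The medians run from -1.37 (pancreas acinar) to 1.60 (male-biased), and 19 lie outside the grey bars (filled points).

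Metabolic lists moved in opposite directions. Of 13 lipogenesis and glucose use genes 10 were higher in replicate 2 and 2 lower, of which 1 under all scalings (median 0.45, or 0.29 once a trend with GC content and length was removed, 12 adjusted over the list alone), Scd1 by 0.60 and Fasn by 0.48 on the log2 scale. Of 21 amino acid catabolism genes 19 were lower, 17 under all scalings, and 1 higher (median -0.37, 20 adjusted over the list alone), with Gls2 at -0.78 and Hpd at -0.47. Of 16 pericentral genes, expressed near the central vein, 12 were lower, 9 under all scalings, and 1 higher (median -0.35, 13 adjusted over the list alone), with Oat at -0.86 and Glul at -0.43. Of 14 periportal genes 10 were lower, 8 under all scalings, and 4 higher (median -0.29, 14 adjusted over the list alone), with Gls2 at -0.78 and Cyp2f2 at 0.24. Periportal genes lay inside the random range with TPM ratios (percentile 3.91) and without the most abundant member (percentile 2.605). Of 7 urea cycle genes all were lower with TMM and 5 under all scalings, Cps1 not among these (median -0.30, percentile 5.905, 7 adjusted over the list alone). Of 19 fatty acid oxidation genes 17 were lower with TMM but only 11 under all scalings (median -0.21, percentile 3.70, 17 adjusted over the list alone), and the list lay outside the random range with TPM ratios (percentile 1.865) and without its most abundant member (percentile 0.92). Of 6 gluconeogenic genes 4 were lower and 1 higher (median -0.29, percentile 6.37, 5 adjusted over the list alone), with Pck1 at -1.39.

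Clock, early response and histone lists also differed. The 5 clock genes that peak with Bmal1 were all lower in replicate 2 with TMM and 4 under all scalings, Clock being the exception (median -0.52, 5 adjusted over the list alone), with Nfil3 at -1.13 and Arntl, the Bmal1 gene, at -0.52. The clock genes that peak with Dbp and Per had a median of 0.23 (percentile 97.1, 4 of 10 higher and 3 lower, 7 adjusted over the list alone), with Nr1d1 at 0.34 and Dbp at 0.85. Immediate early genes had a median of 0.34 (5 of 12 higher and 4 lower, 9 adjusted over the list alone), although the 3 most abundant, Zfp36 (-0.57), Dusp1 (-0.95) and Junb (-0.63), were lower, and the list lay inside the random range with TPM ratios (percentile 83.8). Proliferation genes had a median of -0.46 (5 of 14 lower, 4 under all scalings, 1 higher, 6 adjusted over the list alone), with Tk1 at -0.75, and percentile 2.70 with TPM ratios. Mitochondrially encoded mRNAs had a median of -0.38 (12 of 13 lower, 9 under all scalings, 13 adjusted over the list alone), with mt-Cytb at -0.69 and mt-Co1 not among the 9, and came inside the random range once a trend with GC content and length was removed (median -0.20, percentile 10.1). Replication-dependent histones, whose mRNAs mostly lack a poly-A tail, had a median of -0.68 (21 of 31 lower, 18 under all scalings, 1 higher, 22 adjusted over the list alone), with Hist1h2bc at -0.59. Histone genes come in similar copies, so their split is uncertain. Small structural RNAs had a median of 0.71 (4 of 6 higher, 1 lower with TMM only, 5 adjusted over the list alone), with Rn7sk at 0.58. The 4 include Rn7s1 and Rn7s2 (each 1.31), near-identical copies listed with equal reads, so these are not separate measurements. Inside the random range lay plasma proteins (median -0.10, 5 higher and 19 lower of 26, 9 of the lower under all scalings, 24 adjusted over the list alone), coagulation (median -0.06, 5 higher and 9 lower of 15, 4 of the lower under all scalings, 14 adjusted over the list alone), complement (median 0.02, 8 higher and 5 lower of 16, 3 of the lower under all scalings, 13 adjusted over the list alone), acute phase (median -0.05, 6 higher and 8 lower of 17, 5 of the lower under all scalings, 14 adjusted over the list alone) and major urinary proteins (median -0.07, 6 higher and 8 lower of 17, 14 adjusted over the list alone). So did xenobiotic cytochromes P450 (median -0.10, 5 higher and 9 lower of 15, 4 of the lower under all scalings, 14 adjusted over the list alone), conjugating enzymes (median -0.15, 5 higher and 8 lower of 16, 6 of the lower under all scalings, 14 adjusted over the list alone), bile acid genes (median -0.01, 8 higher and 7 lower of 18, 3 of the lower under all scalings, 15 adjusted over the list alone), cholesterol genes (median 0.03, 9 higher and 8 lower of 19, 3 of the lower under all scalings, 17 adjusted over the list alone) and iron and heme genes (median -0.11, 4 higher and 5 lower of 12, 4 of the lower under all scalings, 12 adjusted over the list alone). The same held for endocrine genes (median -0.15, 5 higher and 10 lower of 16, 7 of the lower under all scalings, 15 adjusted over the list alone), liver transcription factors (median -0.12, 6 higher and 15 lower of 25, 10 of the lower under all scalings, 22 adjusted over the list alone), heat shock genes (median -0.24, 0 higher and 7 lower of 9, 4 of the lower under all scalings, 7 adjusted over the list alone), fetal liver genes (median -0.10, 1 higher and 2 lower of 6, 3 adjusted over the list alone) and cytosolic ribosomal proteins (median -0.07, 25 higher and 40 lower of 80, 15 of the lower under all scalings, 67 adjusted over the list alone). The balance of directions turned with the scaling for several of these lists, as for plasma proteins (14 higher and 11 lower with total reads) and ribosomal proteins (40 higher and 19 lower). Heat shock genes had 3 higher and 4 lower with total reads and with spike-in totals. Once the trend with GC content and length was removed, complement (percentile 98.6) and ribosomal proteins (percentile 99.8) lay above the random range, and urea cycle (percentile 2.015) and fatty acid oxidation genes (percentile 1.755) below it. Median and mean differed in sign for cholesterol (mean -0.01), bile acid (0.10), cytochrome P450 (0.07), iron and heme (0.02), endocrine (0.11) and stellate cell (-0.07) genes.

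Spike-in RNAs were also compared between the libraries, but their spread was not used to judge the differences above. Of the 96 spike-ins listed, 77 had reads, and they made up 1.80% of reads in replicate 1 (95% Wilson interval 1.797% to 1.804%) and 1.765% in replicate 2 (1.762% to 1.768%). Over 61 spike-ins with at least 20 reads the median log2 ratio of replicate 2 over replicate 1, relative to total gene reads, was 0.03 with an SD of 0.27 across spike-ins. Their levels covered 4.12 orders of magnitude.

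The list of splice junctions made for the whole series, on the older build mm9, held 352887 junctions and 50489716 reads, 24692822 and 25796894 of them from the libraries the file calls R1 and R2. Only 41.0% of junctions had reads in both libraries, but these held 99.3% of junction reads, and 37.6% of junctions rested on a single read. The 5 junctions with most reads all lay on the plus strand of chromosome 5 between 90890805 and 90904294 (mm9) and together held 6.03% of junction reads. The most read, 90901170 to 90901486, had 836266 reads (356444 in R1 and 479822 in R2), followed by 90903726 to 90904294 (833093 reads), 90896500 to 90897506 (593889), 90897722 to 90898527 (459941) and 90890805 to 90891725 (323165). Across junctions read in both libraries Spearman's rho was 0.904.

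The list of transcribed contigs, also on mm9, held 411452 contigs that covered 148 Mb, 74.5 Mb on the plus and 73.5 Mb on the minus strand, with a median length of 230.0 bases. The highest authors' level, 30700, belonged to a 434-base contig on chromosome 16 (11143991 to 11144424, plus strand), followed by 9220 on chromosome 9 (110183743 to 110183883), 8970 on chromosome 17 (39979936 to 39985775), 8540 on chromosome X (84483689 to 84483769) and 5970 on chromosome 3 (5860319 to 5860830). On chromosome Y 22 contigs were listed, with a highest level of 1.39, and 16 junctions with 18 reads in all, 0 of which had reads in both libraries. Chromosome X had 9945 contigs. Gene names for mm9 positions are not used here because the annotation at hand is for another build.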

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

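List medians with total reads, the reproducibility score of 0.1 and the count of lists at 1% or more of TPM were chosen after the data were seen. Genes detected in both libraries numbered 7011 at TPM 5 against 10701 at TPM 1, by construction of the limit, and 10836 to 13952 under the other limits and the rescaled TPM. With either library left out the number was 10907 to 11317. The share of the 10 most abundant genes was 19.0004% when taken from reads, not corrected for length, against 21.7% of TPM. Replicate correlation was 0.969 with pseudocount 0.1, 0.992 over all genes listed and 0.969 at mean TPM 10 or more. The coefficient of variation was 20.96% with at least 200 reads and 21.7% from the trended dispersion. The same top isoform was found for 86.9% of genes at mean TPM 1 or more and 97.6% where it held at least 50% of the gene. A reproducibility score of at most 0.1 left 124475 junctions, with 99.1% of the reads, and 201373 contigs. The cause of the other differences was not tested.

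Genes that differed between libraries numbered 7207 to 8622 over the alternatives. With total reads 6814 of the 8301 remained and with spike-in totals 6602, and the share of calls higher in replicate 2 went from 49.7% to 69.4% and 73.6%. Lists outside the random range numbered 16 to 19, the same 19 with DESeq2 size factors and with total reads, 15 of them with TPM ratios and 18 without the most abundant member. Lists at 1% or more of TPM numbered 8 to 10. With shares taken from reads, 38 of 47 list shares moved by at least their SD and 9 did not. With total reads 10 list medians inside the random range changed sign, and 0 of those outside it. Depth limits low genes: muscle, adipocyte and mesothelial markers rest on few reads. No value without a replicate could be had for comparisons between the libraries, and no paired analysis was possible because there is 1 group.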

Other observations

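The tests of chromosome Y, of the hepatocyte share and of male tissue were chosen only after the result was seen, and the form of the GC and length correction was settled after a first run. Apart from Cyp26a1, Cyp2c39, Mt2, Igf1 and Eno1b, the single genes of this and the next paragraph were picked after their values were seen, so they do not stand for any pathway, and no enrichment was tested. Besides Cyp26a1 (12971 and 479 reads) and Cyp2c39 (18359 and 208 reads), Cyp26b1, a retinoic acid hydroxylase, had 1207 reads in replicate 1 and 37 in replicate 2 (log2 ratio -5.15), the retinoic acid receptor Rarb 398 and 174 (-1.34) and the retinol acyltransferase Lrat 1682 and 754 (-1.30). Not all genes of retinoid handling differed this much, with Dhrs3, a retinaldehyde reductase, at -0.17.

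Beside Mt2, the metallothionein Mt1 had 1439 and 341 TPM (log2 ratio -2.17). Lower in replicate 2 by the exact test were also Igfbp1 at 42.6 and 14.8 TPM (-1.65), the tyrosine aminotransferase Tat at 1183 and 747 TPM (-0.79), Fkbp5 at 25.1 and 15.1 TPM (-0.84) and Tsc22d3 at 86.1 and 48.3 TPM (-0.94). Sgk1, like these a gene known to respond to glucocorticoids, had a ratio of -0.16 (adjusted p = 0.060, exact test). Higher in replicate 2 were Cish at 8.49 and 28.2 TPM (1.62) and Socs2 at 16.9 and 46.7 TPM (1.21), which growth hormone is known to induce, whereas Igf1, also known to be induced by it, was lower (-0.28). Eno1b had 53 and 10150 reads, while Eno1, its parent gene, had 26150 and 25583 reads (-0.18). Eno1 thus did not lose as many reads as Eno1b gained. Whether reads were shared between these copies was not tested, so the Eno1b value remains uncertain.

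The state of the animals, such as hormones or immune activity, was not tested for the patterns weighed next, because the design has 1 group.

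The first pattern is the absence of reads on Y-linked genes in libraries labelled as pooled from both sexes. A reference without chromosome Y is argued against only weakly, by the 1 read assigned there in replicate 2. The gene tables list 1569 genes of that chromosome, the 4 Y-linked genes among them. This shows what was annotated, not whether reads could be placed there. A depth too low for a mixed pool is argued against as well, provided that male tissue is read at Y-linked genes about as much as at their X-linked homologues. The limit of 3 reads is 0.00901% of the reads on these 4 homologues, far below the male share of a mixed pool. That the sequenced tissue was female, against the label, is a candidate explanation. The 1 read on all genes of chromosome Y is the pattern itself, so it is no separate evidence for this. Xist had 18451 and 26061 reads in replicates 1 and 2, but a mixed pool would also contain Xist. The mm9 lists of the series hold 16 junctions with 18 reads on chromosome Y, 0 of them read in both libraries. They also hold 22 contigs there, 2 of them at a reproducibility score of at most 0.1.

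The second pattern is the higher level of Kupffer cell and interferon genes in replicate 2. A lower share of hepatocyte RNA would raise the markers of other cell types alike. The median log2 ratio of 11 Kupffer cell genes exceeded that of the 40 genes of the other non-hepatocyte lists by 0.59. This was at mean TPM 1 or more (p = 0.0043, two-sided permutation test), where the 8 lists also differed (p = 0.0001, Kruskal-Wallis test by permutation). Over all members tested, Kupffer cell genes exceeded 13 stellate cell genes by 0.72 (p = 0.0002, two-sided permutation test, 3 comparisons, all unadjusted). These p-values cannot decide on this share, because genes are not independent replicates and Kupffer cell genes were picked for their high ratios here. The medians were 0.74 for Kupffer cell, 1.35 for lymphocyte (3 genes), 1.33 for neutrophil (1 gene), 0.47 for red blood cell, 0.35 for sinusoidal endothelial, 0.03 for stellate cell, -0.20 for cholangiocyte and -0.82 for mesothelial genes (1 gene). The lists thus did not move alike, but whether this share is the whole cause is left open. A trend with GC content and transcript length is argued against as the whole cause, since after its removal the medians were 0.77 for Kupffer cell and 0.96 for interferon genes, above all 10000 random lists. More or more active macrophages or other immune cells in the tissue of replicate 2 may underlie the pattern and remain untested.

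The third pattern is that male-biased genes were higher and female-biased genes lower in replicate 2. Dilution of female by male tissue would lower Xist, which was higher in replicate 2 (log2 ratio 0.35, adjusted p = 5.1e-143, exact test). That p-value covers counting error only, and the coefficient of variation between the libraries was 24.1%. Xist as 1 gene therefore cannot decide on dilution. A male share behind the male-biased genes is argued against, under the proviso on Y-linked genes given for the first pattern. The added 273 TPM of this list needs a share of at least 0.0273%, were all male RNA from it, and 3 reads allow 0.0174% in replicate 2. Reads shared between paralogs are argued against as the whole cause, as members with a posterior SD of at most 1% of their reads kept medians of 0.82 (10 male-biased, against 1.60 over all 13) and -0.92 (15 female-biased), and after removal of the GC and length trend the full lists had medians of 1.67 and -0.92. A difference in hormonal state may underlie the pattern and remains untested.

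GC content and length correlated with the log2 ratio across genes, which are not independent replicates, at Spearman's rho of 0.08 and 0.09. Removal of their trend left 17 of the 19 lists outside the random range and brought 21 outside in all. Mitochondrially encoded mRNAs (median -0.20, percentile 10.1) and cholangiocyte genes (median -0.18, percentile 10.5) came inside it. Complement (median 0.07, percentile 98.6), ribosomal protein (0.01, 99.8), urea cycle (-0.35, 2.015) and fatty acid oxidation genes (-0.24, 1.755) came out of it.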
